A study of Mus musculus with 4 samples.

How the data were processed

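RNA of primary mouse Th17 cells (strain C57BL/6NJ) was measured in 4 RNA-seq libraries, biological replicates 1 to 4 in the labels, all in 1 group. The deposited files hold raw fragment counts per gene, which per the file headers were made with featureCounts 1.4.6-p4 from paired-end alignments with the GENCODE vM13 annotation. The genome build is mm10 per the labels. Per the file headers, fragments were counted over exons and summed per gene, both ends had to be aligned, and the strand option was 2 (reverse), so antisense genes are told apart. The options for counting fragments that align to several places, or that overlap several genes, do not appear in those headers, and by the program's default both kinds are left out. If that default was used, genes with near-identical copies and overlapping genes are undercounted. The alignment names in the headers carry the tag star2, and the aligner's version is not given in the sources used here. The output names in the headers carry a tag of 16 hr, which the labels do not explain. The files also give each gene's summed exon length, used here.

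Each file lists 50600 genes, of which 50376 matched a symbol and class in the GENCODE M21 annotation (mm10) with the version of the identifier ignored, and 20704 had a fragment in some library. No row named anything other than a gene. Coordinates are from that annotation or the count files, both on mm10. The designs were written before the data were examined and assumed expected counts with posterior means. The files hold whole counts instead, so the count test was run on them as deposited, and TPM was computed here as count over exon length, scaled to 1000000 per library. The exon length is that of all isoforms together, which lowers the TPM of genes with long unused exons. The filter of the variability test asks for about 10 fragments, scaled to library size, in every library, so genes low in some libraries were not tested. Alternatives that needed posterior means were not run.

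Libraries held 24696730 to 37025016 fragments. A count of 3 fragments was taken as the floor for genes with none or few. It corresponds to between 0.275 and 0.409 TPM for a gene of 1 kb, and floors in the text are for the shallowest library.

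In all, 39 gene lists were written before the data were examined, and 3 symbols on them found no match. Within-library contrasts used log2(TPM + 1) with an exact two-sided sign-flip test over 4 libraries and Benjamini-Hochberg adjustment within each of the families of contrasts, after removal of genes shared by the lists compared. A fold on this scale understates the difference for low genes. Replicates were compared by correlation across genes and by chi-square over genes with at least 10 fragments in the pair.

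Variability between replicates was tested with edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, glmQLFit with an intercept only, the robust prior and the older deviance estimate). Each gene's residual quasi-dispersion over the trended prior was referred to the F distribution, upper tail, with the largest prior degrees of freedom, 24.8, for every gene. Those last 2 settings were fixed before the first run but after the written design. TMM factors lay between 0.995 and 1.003. On simulated counts, 200 genes among 11728 were given extra spread, all of them with a mean above 200 fragments. The test recovered 60% of genes with a log2 SD of 0.25 and 89% with 0.5, and 4 of its 153 calls were false. Recovery at lower counts was not measured. Simulated genes otherwise followed the fitted trend exactly, without the scatter of real genes around it, so real data may hold more false calls. List co-variation was the SD over libraries of a list's mean log2 CPM (TMM, prior count 1), as a percentile among 10000 random lists drawn from 50 abundance bins, for lists with at least 5 members. In simulated data, a list shifted by 0.1 reached percentile 100 and 0 of 26 unshifted lists passed 95. Each gene's values were shuffled independently there, so unshifted lists held no shared movement. The simulation therefore does not show how often lists of co-regulated genes pass. Lists among the variable genes were tested with Fisher's exact test against all tested genes.

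Alternatives were a pseudocount of 0.1, TPM rescaled without mitochondrial and ribosomal RNA genes, shares of fragments, list medians, expressed members only, other detection thresholds, DESeq2 1.42.0 size factors, other filters, a prior without robust estimation, limma 3.58.1 (limma-trend), and each replicate left out. Leaving out chromosomes X and Y was added after seeing the data. Shared sequence was measured as the share of a gene's 50-base words found in annotated transcripts of other genes on either strand. Other work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

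Named genes followed a rule set in advance. It takes all lineage regulators and cytokines, the 4 highest and the lowest member of each other list, the 15 most abundant genes that are neither mitochondrial nor ribosomal proteins, and, of variable genes with mean TPM of at least 5, the 15 with the largest F. Some genes that the rule takes, and 1 planned set of 5 contrasts built on such a gene, are not reported here. Il1rn, Rrm2, Top2a, Ccna2, Malat1, Fosl2, Angptl2 and Uty are outside the rule and were named after their values were seen.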

Results

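T-helper 17 (Th17) cells are CD4 T cells that make interleukin-17, and those measured here were primary mouse cells of strain C57BL/6NJ that the labels place in a CD4 T-cell differentiation protocol. There was 1 group of 4 RNA-seq libraries, named here by the biological replicate numbers 1 to 4 in the labels, and no second condition. The comparisons below are therefore between genes within each library and between the 4 replicates. Gene counts summed to 37025016, 24696730, 32766291 and 36798195 fragments in replicates 1 to 4. At TPM (counts over exon length, scaled to the same total in each library) of at least 1 in every library, 11170 genes were detected, of which 9761 were protein coding, and 120 genes reached 1000 TPM in every library. Across the 12738 genes at 1 TPM in some library, Pearson's r of log2(TPM + 1) lay between 0.987 and 0.990 over the 6 pairs of libraries and Spearman's rho between 0.989 and 0.992. These are correlations across genes, which are not independent replicates. Chi-square over its degrees of freedom was 3.41 for replicates 1 and 2, 3.66 for replicates 3 and 4 and between 6.39 and 7.95 in the other pairs, so no pair agreed within sampling noise. It included genes of chromosomes X and Y, which differed most between these pairs (below), and was not computed without them. Each library was counted as 1 sample. The labels give each library its own biosample but a single donor identifier, and do not say whether the cultures came from separate animals. In replicates 1 and 2 against 3 and 4, Xist was at 186 and 161 against 0.687 and 0.721 TPM. The Y-linked gene Ddx3y was at 0.442 and 0.446 against 88.6 and 83.2 TPM. These values argue against 1 animal as the source of all 4 libraries. Within each of these pairs the source is not known, and the spread between libraries may still be partly technical.

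Outside the mitochondrial and ribosomal protein genes, the translation elongation factor Eef1a1 led at 15676 ± 825 TPM (SD, n = 4, as for all values given with ±), followed by the chaperone Hsp90ab1 at 10263 ± 204, the elongation factor Eef2 at 5809 ± 90.4, the nucleolar protein Npm1 at 5287 ± 216 and Actb at 4431 ± 71.4 TPM. The inhibitory receptor gene Ctla4 was also among the 15 most abundant genes, at 2061 ± 85.2 TPM.

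Regulators of the other helper lineages were low. Tbx21, the Th1 regulator T-bet, was at 6.65 ± 0.881 TPM and Gata3, the Th2 regulator, at 1.54 ± 0.128 TPM. Foxp3, the regulator of regulatory T cells, was at 9.92 ± 1.47 TPM and Bcl6, the regulator of follicular helper cells, at 19.97 ± 0.523 TPM. Eomes had 7 fragments over the 4 libraries, a mean of 0.0434 TPM, which is under the 0.0985 TPM that 3 fragments would give in the shallowest library. Runx3 and Zbtb7b, regulators of the CD8 and CD4 fates, were at 62.9 ± 3.07 and 39.5 ± 0.815 TPM. Rora, a nuclear receptor that takes part in Th17 differentiation, was at 110.3 ± 5.99 TPM.

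**Figure D1:**
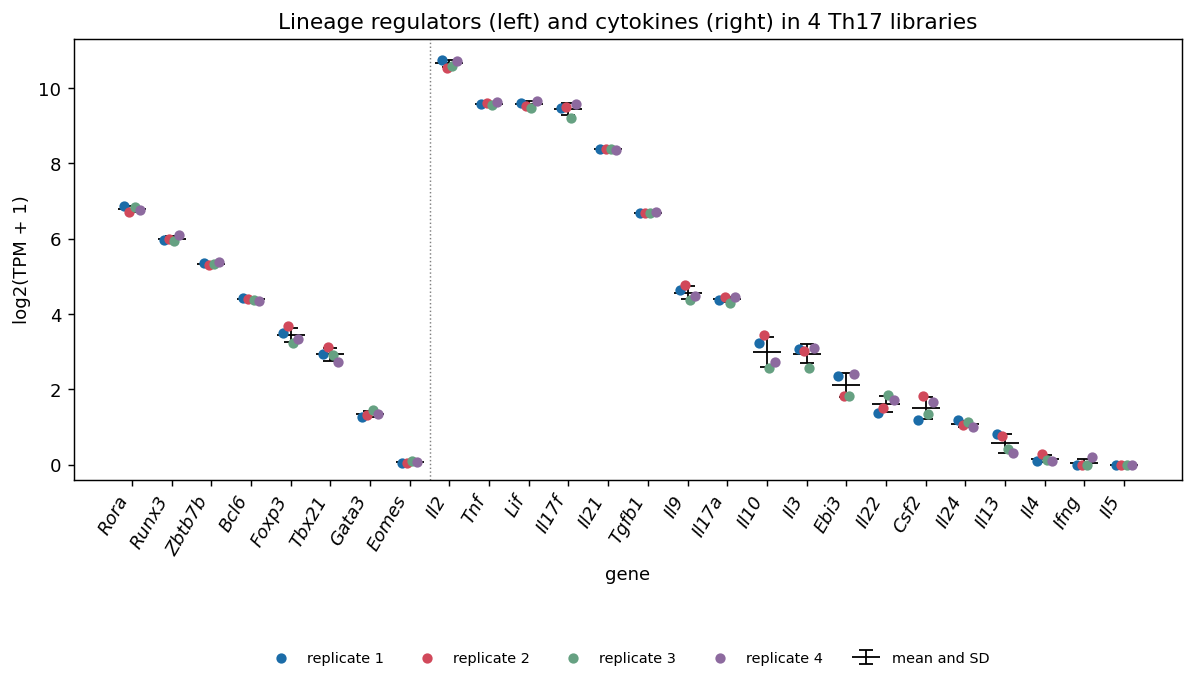
Level of lineage regulators (left of the dotted line) and cytokine genes (right) as log2(TPM + 1), with 1 point per library and the mean and SD of the 4 libraries as bars. Gata3 and Tbx21 sit low among the regulators (1.54 and 6.65 TPM), Il17f exceeds Il17a (694 against 20.02 TPM), and Il5 is at 0 in all 4 libraries.

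Cytokine transcripts were led by Il2, at 1615 ± 114 TPM, Tnf at 768 ± 15.7 TPM and Lif, a cytokine of the interleukin-6 family, at 759 ± 45.7 TPM. Among the Th17 cytokines, Il17f (ENSMUSG00000041872.9, chromosome 1, 20777146 to 20790617 in mm10) was at 694 ± 73.6 TPM and Il21 at 331 ± 4.47 TPM, while Il17a (ENSMUSG00000025929.4, chromosome 1, 20730905 to 20734496), on the same chromosome, was at 20.02 ± 1.02 TPM and Il22 at 2.08 ± 0.464 TPM. Il17f was above Il17a in each library. The cytokines of Th1 and Th2 cells were at or near the limit of detection. Il13 was at 0.503 ± 0.258 TPM. Il4 had 5 fragments and Ifng 2 in all, both under their floors of 3 fragments in the shallowest library, which correspond to 0.334 and 0.316 TPM. No fragment was counted for Il5 in any library, which allows up to 0.266 TPM in the shallowest. Mean log2(TPM + 1) over Il17a, Il17f, Il21 and Il22 was 5.95 ± 0.06, against 0.19 ± 0.06 over Ifng, Il4, Il5 and Il13, a difference of 5.76 ± 0.10 in the same direction in 4 of 4 libraries (exact two-sided sign-flip p = 0.13). Rounded, that is the smallest p that 4 libraries allow, so no within-library comparison here can pass 0.05. Other cytokine genes were Tgfb1 at 102 ± 1.11, Il9 at 22.8 ± 2.88, Il10 at 7.17 ± 2.29, Il3 at 6.78 ± 1.24, Ebi3 at 3.38 ± 0.946, Csf2 at 1.89 ± 0.588 and Il24 at 1.13 ± 0.118 TPM. Floors and intervals of this kind cover counting error only.

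Of the 20 genes of the Th17 core list, 18 were at 1 TPM or more in every library and 11 at 100 TPM or more. Irf4 and Batf, transcription factors that act together at Th17 genes, were at 1647 ± 43.8 and 594 ± 7.16 TPM, and Hif1a, the oxygen-responsive factor, at 564 ± 22.7 TPM. The lowest member was Sox5, at 0.239 ± 0.0595 TPM. In a wider list of 26 transcription and chromatin regulators of Th17 cells, 25 were at 1 TPM or more in every library, with the AP-1 factor Junb at 631 ± 35.1 TPM. Among 18 receptor genes for the cytokines that shape these cells, 17 reached 1 TPM in every library. The interleukin-2 receptor chains Il2ra and Il2rb were at 1189 ± 11.5 and 826 ± 44.7 TPM, the shared chain Il2rg at 290.2 ± 5.04 TPM and the signalling chain Il6st at 218 ± 5.67 TPM, whereas Il10ra was at 0.366 ± 0.1696 TPM.

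Lists of genes tied to other helper subsets lay below the Th17 core list, by margins that differed between subsets. The mean log2(TPM + 1) of the core list was 5.80 ± 0.02, that of the Th1 list 1.81 ± 0.01 and that of the Th2 list 2.83 ± 0.04. The Treg list was at 4.67 ± 0.03 and the naive and memory list at 5.33 ± 0.07, and against the follicular helper list, after removal of the shared gene Il21, the core list was at 5.66 ± 0.02 and the other at 4.46 ± 0.01. The core list exceeded the Th1 list by 3.99 ± 0.02, the Th2 list by 2.96 ± 0.05, the follicular helper list by 1.20 ± 0.03, the Treg list by 1.13 ± 0.04 and the naive and memory list by 0.47 ± 0.09. Every difference had its direction in 4 of 4 libraries (exact two-sided sign-flip p = 0.13, and 0.13 after Benjamini-Hochberg adjustment over the 5). The size depends on which genes the lists hold. With the list median in place of the mean, the margin over the naive and memory list was 2.08 and that over the Treg list 2.77, and with members under 1 TPM left out the margin over the Th2 list was 1.47.

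Single members of those lists were abundant. In the Treg list, Ctla4 was followed by Il2ra and by Tnfrsf4, which encodes the costimulatory receptor OX40, at 1092 ± 32.5 TPM, and Tnfrsf18 (GITR) was at 133 ± 7.89 TPM, all 4 of which activated T cells also express. Klrg1 had no fragment, with a floor of 0.289 TPM. In the Th2 list, the chemokine receptor Ccr8 was at 392 ± 25.7, the phosphatase Dusp4 at 251 ± 11.1, Stat6 at 209.7 ± 2.04 and Il4ra at 166 ± 8.25 TPM. In the follicular helper list, Pdcd1, which encodes PD-1, was at 420.2 ± 7.201, the octamer coactivator Pou2af1 at 169 ± 2.198 and Icos at 152 ± 9.91 TPM, with Cebpa under its floor of 0.155 TPM. In the naive and memory list, Ccr7 was at 529 ± 20.5, Igfbp4 at 488 ± 24.9, Tcf7 at 380.3 ± 6.33 and Bach2 at 311 ± 11.7 TPM, and the lowest member was Klf3 at 2.26 ± 0.225 TPM. In the Th1 list, which also holds Runx3, Cxcr3 was at 12.8 ± 1.44 and Nkg7 at 11.4 ± 2.25 TPM.

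Genes tied to tissue-damaging (pathogenic) Th17 cells lay below genes tied to Th17 cells that make interleukin-10 (regulatory). Over 16 and 10 genes, the mean log2(TPM + 1) was 2.63 ± 0.06 and 5.52 ± 0.12, and pathogenic minus regulatory was -2.89 ± 0.11, negative in 4 of 4 libraries (exact two-sided sign-flip p = 0.13). The regulatory list was led by Ctla4, Il6st, Maf at 206 ± 8.87 and Ahr at 179 ± 8.002 TPM, and its lowest member was Il4. Maf and Ahr are also in the Th17 core list, and Il10 itself was at 7.17 ± 2.29 TPM. A list's level is set by which genes it holds, and there was no second condition. The difference therefore does not class these cells as regulatory or pathogenic. In the pathogenic list, Lag3 at 174 ± 7.49 and Icos exceeded 100 TPM in every library. The chemokine genes Ccl4 and Ccl3 were at 70.4 ± 8.27 and 9.25 ± 1.17 TPM, and Cxcl3 was under its floor of 0.117 TPM.

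Genes of T-cell activation, the T-cell receptor and central metabolism were abundant in all 4 libraries. Of 24 activation and costimulation genes, 22 reached 10 TPM in every library, including Myc at 972 ± 13.4 TPM, while Havcr2 was under its floor of 0.150 TPM. All 18 genes of the T-cell receptor complex list were above 10 TPM, with Cd5 at 1843 ± 46.5, Cd6 at 1342 ± 26.1, Trac at 1289 ± 61.9 and Lat at 922 ± 46.0 TPM, and Cd3g the lowest at 48.0 ± 5.19 TPM. Among 17 glycolysis genes, Ldha was at 3198 ± 99.9, Pkm at 2032 ± 34.6, Gapdh at 1259.9 ± 57.2 and Aldoa at 1085 ± 42.3 TPM, and Slc16a3 the lowest at 6.95 ± 0.857 TPM. All 19 genes of oxidative phosphorylation were above 10 TPM in every library, from Atp5b at 1645 ± 26.7 to Ndufs1 at 60.6 ± 1.62 TPM. All 20 cholesterol synthesis genes were above 1 TPM, from Cyp51 at 139 ± 3.33 to Fdps at 10.1 ± 0.517 TPM. In the list of 18 genes of the unfolded protein and amino acid stress responses, the chaperones Calr and Hspa5 were at 1752 ± 23.4 and 1281 ± 22.2, Atf4 at 924 ± 24.3 and Hsp90b1 at 834 ± 12.6 TPM, and Slc7a11 was under its floor of 0.0294 TPM. The heat shock and early response list was led by Hspa8 at 3289.9 ± 81.9, Hspd1 at 2079 ± 58.3 and Hsp90aa1 at 1289 ± 23.7 TPM, while the inducible chaperone gene Hspa1a was under its floor of 0.138 TPM. In the hypoxia list, Egln3 was at 368 ± 23.1, Ero1l at 128 ± 1.68, Slc2a1 at 103 ± 3.34 and Hilpda at 72.5 ± 3.58 TPM, with Adm under its floor of 0.253 TPM. Of 21 interferon response genes, 8 reached 1 TPM in every library. Bst2 was at 227 ± 3.29 TPM, Irf1 at 22.6 ± 1.62 and Gbp2 at 13.2 ± 1.08 TPM, and Ifi44 had no fragment, with a floor of 0.0668 TPM. In the list of apoptosis and p53 genes, Bax was at 377 ± 17.04, Mcl1 at 316 ± 9.68, Ccng1 at 276 ± 19.5 and Bcl2l1 at 230.4 ± 6.73 TPM, and Gadd45a the lowest at 0.894 ± 0.149 TPM.

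Members of the 22-gene cell cycle list differed widely in level, and 20 reached 1 TPM in every library. The replicative helicase subunits Mcm3, Mcm5 and Mcm6 were at 641 ± 35.2, 525 ± 27.0 and 463 ± 13.2 TPM and the polymerase clamp Pcna at 439.7 ± 17.2 TPM. The kinetochore gene Cenpf, the lowest member, was at 0.478 ± 0.0264 TPM. In the trafficking receptor list, 17 of 21 genes reached 1 TPM in every library, with the integrin genes Itgal at 560.2 ± 22.95 and Itgb1 at 146 ± 3.04 TPM beside Ccr7 and Ccr8. Ccr9 was the lowest, under its floor of 0.0399 TPM.

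Markers of other cell types were at or near 0. Of 103 distinct genes in 9 such lists, 10 reached 1 TPM in every library, 2 reached 10 TPM, and 41 had no fragment in any library. Those above 10 TPM in every library were Id2, at 336 ± 16.3 TPM, and the immunoglobulin heavy chain gene Ighm, at 54.8 ± 4.13 TPM. Id2 is a regulator of innate lymphoid cells that T cells also express. The B-cell receptor gene Cd79a was at 0.343 ± 0.107 and Ighd at 0.605 ± 0.267 TPM. Igkc was under its floor of 0.769 TPM and Cr2 had no fragment (floor 0.0505 TPM). Cd68 led the myeloid list at 5.24 ± 1.02 TPM and C1qa had no fragment (floor 0.394 TPM). Cd74, which antigen-presenting cells express highly, was at 8.19 ± 1.57 TPM with the class II gene H2-Ab1 at 0.542 ± 0.164 TPM. Nkg7 and Cd8b1 led the CD8 and cytotoxic list, Nkg7 at 11.4 ± 2.25 TPM (8.21 in replicate 2) and Cd8b1 at 7.32 ± 1.16 TPM. In the neutrophil and mast cell list Kit was at 2.43 ± 0.627 TPM and S100a8 had no fragment (floor 0.590 TPM). The highest gene of the gamma delta T-cell list was Trdc at 5.17 ± 0.584 TPM, that of the erythroid and platelet list Itga2b at 0.642 ± 0.0832 TPM, and those of the stromal and epithelial list Pecam1 at 3.24 ± 0.158 and Epcam at 1.52 ± 0.688 TPM. The haemoglobin gene Hba-a1 had no fragment (floor 0.504 TPM).

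By gene class, 98.9% ± 0.06 of fragments fell in protein-coding genes, 0.27% ± 0.06 in long intergenic noncoding RNAs and 0.034% ± 0.001 in ribosomal RNA genes. Genes of the mitochondrial chromosome, some of which are also counted in these classes, held 0.91% ± 0.04 of fragments. Ribosomal protein genes held 13.7% ± 0.17 of TPM, led by Rplp1 at 9377 ± 263, Rpl8 at 8053 ± 256, Rpl4 at 6558 ± 124 and Rplp0 at 6190.2 ± 168 TPM, and Rpl5 was the lowest of the 22 listed, at 377 ± 11.9 TPM. The labels call the assay total RNA-seq, while the library protocol they link is named for polyadenylated RNA. Replication-dependent histone mRNAs, which lack a poly(A) tail, were near 0. The 68 genes named as members of the histone clusters held 0.00266% ± 0.00014 of TPM, and of 21 listed, Hist1h4i at 3.39 ± 0.142 and Hist1h4d at 3.03 ± 0.792 TPM were the highest and Hist1h2ac had no fragment (floor 0.860 TPM). Of 15 other noncoding RNAs without a poly(A) tail, 3 reached 1 TPM in every library. They were Snora73b at 133 ± 15.3 TPM, whose position inside a host gene makes its value uncertain, Rpph1 at 20.96 ± 3.77 TPM and the 7SK RNA gene Rn7sk at 9.26 ± 4.48 TPM. Rmrp had 8 fragments and Rnu12 none (floor 2.71 TPM). Among long noncoding RNAs, Gas5 was at 329.7 ± 21.5, Snhg1 at 222 ± 4.55, Snhg12 at 155 ± 7.97 and Gm26917 at 125 ± 5.66 TPM, and Rmst had no fragment (floor 0.0551 TPM). Of the 13 mitochondrial mRNAs, 7 were above 1 TPM, led by mt-Co1 at 6948 ± 381, mt-Nd1 at 5559 ± 197, mt-Cytb at 3791 ± 228 and mt-Nd2 at 3582 ± 135 TPM, and 6 were under 1 TPM, with mt-Atp8 at no fragment (floor 2.01 TPM).

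The replicates differed most in genes of the sex chromosomes. Xist (ENSMUSG00000086503.3, chromosome X, 103460375 to 103483217), the RNA that silences an X chromosome in cells with more than 1, was at 186, 161, 0.687 and 0.721 TPM in replicates 1 to 4. The Y-linked gene Ddx3y (ENSMUSG00000069045.11, chromosome Y, 1260771 to 1286629) was at 0.442, 0.446, 88.6 and 83.2 TPM, and Eif2s3y at 0.287, 0.328, 86.7 and 71.4 TPM, in the same order. Of 11847 genes tested, 36 varied between the 4 replicates more than genes of their abundance (edgeR quasi-likelihood fit, adjusted p under 0.05, one-sided), and 674 had an unadjusted p under 0.05. If the test is well calibrated, chance alone puts about 1 in 20 of the genes tested under that unadjusted limit. The common biological coefficient of variation was 5.43%. Of the 36, 4 lay on chromosome X and 2 on Y. The adjusted p was 1.08e-30 for Xist, 3.87e-25 for Ddx3y and 2.89e-24 for Eif2s3y. The other X-linked genes were Eif2s3x at 156, 159, 100.1 and 103 TPM in replicates 1 to 4, Kdm5c at 139, 143, 94.4 and 91.3 TPM and Kdm6a at 35.3, 32.2, 20.6 and 19.6 TPM. These 3 are known to be expressed from both X chromosomes. The labels give sex as not collected, so no groups of libraries were formed and compared.

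**Figure D2:**
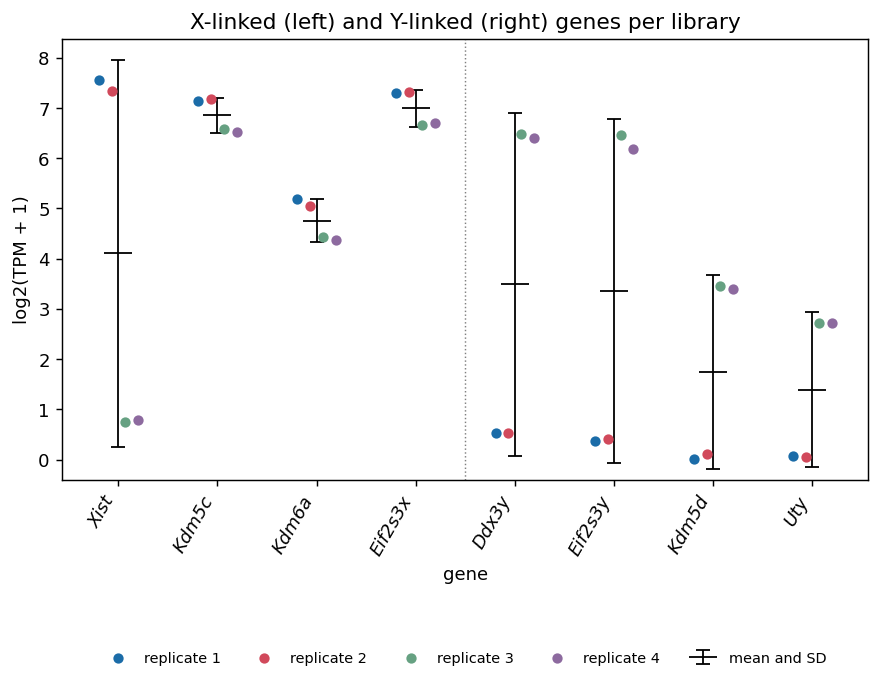
Level of 4 X-linked genes (left of the dotted line) and 4 Y-linked genes (right) as log2(TPM + 1), with 1 point per library and the mean and SD of the 4 libraries as bars. Replicates 1 and 2 sit high for Xist (186 and 161 TPM) and low for Ddx3y (0.442 and 0.446 TPM), and replicates 3 and 4 the reverse (0.687 and 0.721 TPM for Xist, 88.6 and 83.2 TPM for Ddx3y).

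The cell cycle list held 4 of the 36 out of 22 tested (Cdc6, Rrm2, Top2a and Ccna2), against 36 of 11847 genes in all (one-sided Fisher's exact test p = 5.05e-07, adjusted over 27 lists 1.36e-05), and 8 adjusted over the list alone. Fisher's test takes genes as independent, while members of this list moved together between replicates, as described below. All 4 were highest in replicate 4, so the p is likely too small, and the test was not repeated without that library. The replication licensing factor Cdc6 was at 29.4, 34.6, 26.9 and 41.3 TPM in replicates 1 to 4 (edgeR adjusted p = 0.0015) and Uhrf1, which maintains DNA methylation at replication, at 189, 208, 174 and 230.0 TPM (edgeR adjusted p = 0.0019). Both were highest in replicate 4. Without it neither passed the threshold (F fell from 18.6 to 6.97 and from 17.9 to 11.5), and 15 genes passed in place of 36. The long noncoding list held 2 of the 36 (Xist and Malat1, of 9 tested, Fisher's exact test p adjusted over 27 lists 0.0043), and no other list passed. Xist belongs to the sex chromosome pattern above, and the test was not run without it. Of the Th17 core list, Il17f alone was among the 36, at 703, 724, 589 and 759 TPM (edgeR adjusted p = 0.0078), and 2 genes adjusted over the list alone. Il17f did not pass without replicate 3 (F 1.99 in place of 14.1), without replicate 4 (F 12.2) or with a prior not estimated robustly (F 13.3). Tbx21, Gata3, Foxp3 and Bcl6 were tested and were not among the 36. Fosl2, of the wider list of Th17 regulators, was, at 53.0, 61.5, 51.9 and 49.4 TPM (edgeR adjusted p = 0.015). So was Angptl2, of the follicular helper list (edgeR adjusted p = 0.0042). Fosl2 and Angptl2 were not followed in the alternatives. The membrane protein gene Emp1 was at 36.7, 40.7, 29.1 and 26.6 TPM (edgeR adjusted p = 8.16e-04) and Pink1, a mitochondrial quality control kinase, at 19.8, 17.4, 10.99 and 10.7 TPM (edgeR adjusted p = 0.0029), and the latter did not pass without replicate 1 (F 11.2 in place of 16.6). Lars2, the mitochondrial leucyl-tRNA synthetase gene, was at 118, 103, 72.3 and 63.6 TPM (edgeR adjusted p = 4.14e-10). Gm42047 was at 41.1, 33.3, 15.8 and 23.99 TPM, Gm24187 at 854, 713, 522 and 397 TPM and Gm23935 at 2306, 2695, 2097 and 1699.7 TPM. These Gm genes and ENSMUSG00000094114.1 are short or little-studied loci whose counts can include reads of repeated sequence, so their values are uncertain. Shared sequence was not measured for these loci or for Lars2, so reads of repeated sequence were not excluded for Lars2 either. Those loci, Lars2, Emp1 and Pink1 lie outside chromosomes X and Y. Each was nevertheless higher in replicates 1 and 2 than in 3 and 4, the split seen for Xist, whereas Cdc6, Uhrf1 and Il17f did not follow that split. ENSMUSG00000094114.1, at 30.9, 27.7, 13.99 and 19.5 TPM, did not pass without replicate 3 (F 10.3 in place of 19.3), Gm24187 without replicate 1 or 4 (F 11.001 and 10.5 in place of 16.7), and Gm23935 without replicate 2 or 4 (F 11.2 and 6.34 in place of 16.7) or with a prior not estimated robustly (F 15.9).

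Of 27 lists, 9 moved more between replicates than the 95th percentile of 10000 random lists matched on abundance. Lists of genes drawn at random would give 1.35 on average. The 27 lists are not such draws, since their genes can be co-regulated and some genes stand in more than 1 list. As deviations in log2 CPM from the mean of the 4 libraries, the cell cycle list was at -0.15, 0.13, -0.13 and 0.16 in replicates 1 to 4 (percentile 99.6) and the regulatory Th17 list at 0.10, 0.13, -0.18 and -0.05 (percentile 99.7). In the latter, Il10 was at 8.34, 9.79, 4.89 and 5.67 TPM and Il1rn at 9.11, 9.76, 6.26 and 8.84 TPM. The cholesterol synthesis list deviated by at most 0.07 in size, at -0.07 in replicate 3 (percentile 99.99), and the glycolysis list was at -0.05, -0.01, 0.01 and 0.05 (percentile 98.7). The long noncoding list was at 0.52, 0.36, -0.42 and -0.45 (percentile 99.6). These deviations include Xist, at 186, 161, 0.687 and 0.721 TPM, and their size without it is not given. With chromosomes X and Y, and so Xist, left out, the list was at percentile 100, which does not say how far it moved. These 5 lists stayed above the 95th percentile without any 1 library. The naive and memory list, at 0.11 in replicate 3 (percentile 98.9), fell to percentile 0.05 without that library. The mitochondrial list (percentile 97.7) fell to 73.1 without replicate 2 and 90.2 without replicate 4, the T-cell receptor list (96.3) to 76.6 without replicate 1 and 72.5 without replicate 2, and the ribosomal protein list (96.2) to 41.9, 82.6 and 91.4 without replicates 2, 3 and 4. The Th17 core list was at percentile 54.1, the pathogenic Th17 list at 66.6 and the lineage regulators at 49.2.

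**Figure D3:**
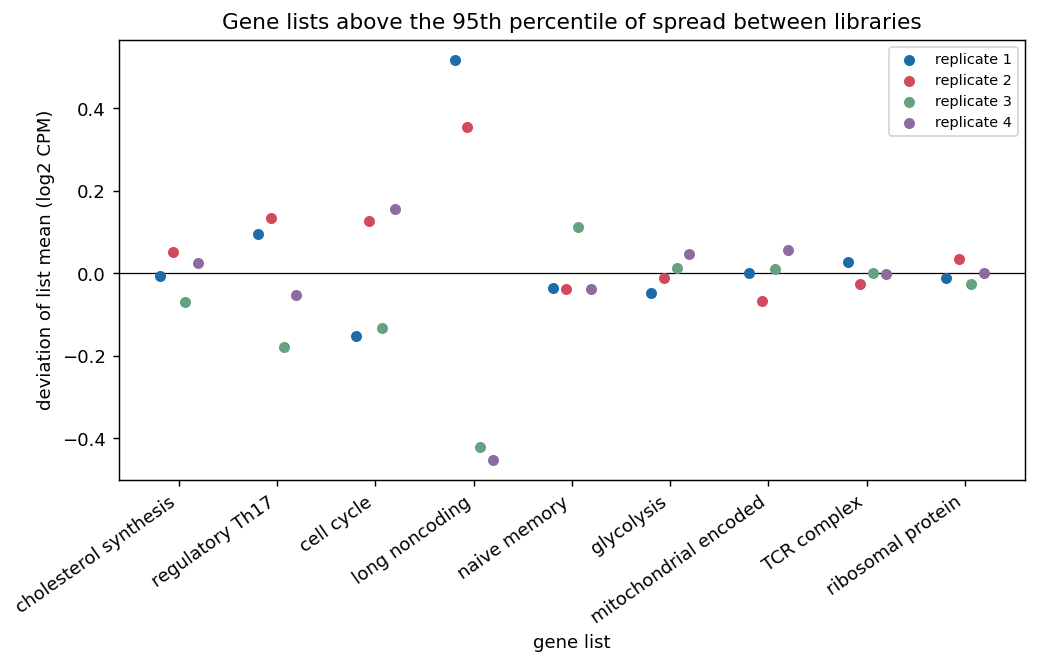
Deviation of each list's mean log2 CPM from the mean of the 4 libraries, for the 9 lists above the 95th percentile of matched random lists, with 1 point per library. The cell cycle list sits at 0.13 and 0.16 in replicates 2 and 4 and at -0.15 and -0.13 in replicates 1 and 3.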

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

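Of the tests in this part, those on replicating cells, on overlap of mt-Atp8 alone, on pooling of both sexes and on a shared day or litter were chosen after the result was seen.

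A library far from the other 3, by its gap to the nearest over the whole range, was found for 10 of 223 values tested, where chance gives about 1 in 20. Replicate 1 stood apart for Hspd1 (1992 TPM, against 2099.6 to 2120.2 in the others). Replicate 2 stood apart for Ighm (48.7 TPM, against 56.2 to 57.5), Tnfrsf4 (1044 TPM, against 1105 to 1113), mt-Co1 (6378 TPM, against 7105 to 7162) and the mean log2(TPM + 1) of the cytokine receptor list (5.50, against 5.47 in the others after rounding). Replicate 3 stood apart for Hist1h4d (4.21 TPM, against 2.57 to 2.78), Il3 (4.93 TPM, against 7.16 to 7.58), the mean log2(TPM + 1) of the cytokine list (4.13, against 4.26 to 4.29) and that of the innate lymphoid list (0.86, against 0.84 in the others). Replicate 4 stood apart for Ptma (2933 TPM, against 2661 to 2669.5).

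Xist was high in replicates 1 and 2 and Y-linked genes in replicates 3 and 4. Pooling of animals of both sexes in each library is argued against, since in no library did the lower of Xist and Ddx3y exceed 0.503% of its highest library. For a day or litter shared by replicates 1 and 2 and by 3 and 4, which no label names, the test decided nothing. Over 8071 genes outside chromosomes X and Y and above 3 log2 CPM, a limit chosen while looking at the data, deviations from the gene means correlated at -0.24 within each of these pairs, under the 0.1 that the test asked for, but above the other pairs (-0.29 to -0.49) and the -0.333 that centring gives where nothing is shared. Source animals of different sex may explain the pattern. Eif2s3x, Kdm5c and Kdm6a, X-linked genes expressed from both X chromosomes, go with this. Each was higher in replicates 1 and 2 than in 3 and 4, for Eif2s3x at 156 and 159 against 100.1 and 103 TPM. The test took Ddx3x and Pbdc1, X-linked genes not looked at before. Their ratios between the lower Xist library and the higher other one were 1.003 and 1.011. These meet the prediction as written in advance (above 1). They do not meet a limit added after they were seen, that they exceed the spread between libraries of up to 3.73%. The test of Ddx3x and Pbdc1 therefore decided nothing, and does not weigh against the explanation. Xist, the Y-linked genes, Eif2s3x, Kdm5c and Kdm6a go with it, but the labels do not give sex.

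Of the 13 mitochondrial mRNAs, 6 were near 0. Overlap with a neighbouring gene is argued against for the 6 as a set by a median of 1.24% of bases overlapped on the same strand in these 6. Loss of reads that align equally well to a nuclear copy is a candidate explanation, since a median of 99.2% of the 50-base words of these genes lay in transcripts of another gene, against 7.61% for the 7 above 1 TPM. Among those 7, mt-Co1 and mt-Nd4 shared 51.1% and 62.2% of their words, at 6948 and 1133 TPM. Under this explanation their values would be undercounted. The exception among the 6 under 1 TPM was mt-Atp8, with 0% shared and 21.08% of bases overlapped. For mt-Atp8, overlap stays open and copies outside annotated transcripts were not searched. No biological explanation was tested, as the design has a single group.

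Replication-dependent histone mRNAs were near 0, with a median of 0.283 TPM over 21 genes. Loss of short transcripts is argued against by 2920.0 TPM for 5 ribosomal protein genes of similar length. Sharing of reads among histone copies is argued against by the 6 histone genes with under 10% shared words, whose median was 0.168 TPM. Selection of polyadenylated RNA is a candidate explanation that stays open, since 8 histone genes with polyadenylated mRNAs had a median of 76.9 TPM. These 8 are not in the replication-dependent list, so their level cannot tell such selection from few replicating cells. Few replicating cells stay open too, since 7 replication genes, most of them induced before DNA synthesis, had a median of 439.7 TPM but the other 15 members of the cell cycle list one of 4.585 TPM, and no other biological explanation was tested.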

How the results depend on the processing

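All choices here were set before the data were examined except leaving out chromosomes X and Y and following Il17f, which was added once it was seen among the variable genes. The 7 within-library contrasts described kept their direction in all 54 alternatives run, which says nothing of significance since 4 libraries cannot pass 0.05. The margin of the Th17 core list ranged from 0.33 to 2.08 over the naive and memory list and from 1.47 to 6.02 over the Th2 list. The count of variable genes, 36, became 94 with no filter beyond 1 fragment and 17 with a prior not estimated robustly, and ranged from 15 (without replicate 4) to 37 with each replicate left out. All 36 were among the 94, and 17 of the 17 and 14 of the 15 were among the 36. Without chromosomes X and Y it was 40, and limma gave 40, sharing 32. Lists above the 95th percentile numbered 14 in place of 9 among genes with a mean TPM of at least 5. The lowest correlation between replicates was 0.959 with a pseudocount of 0.1 and 0.995 over all genes, and ranged from 0.987 to 0.989 with each replicate left out. Markers of other cells numbered 22 in place of 10 at 0.1 TPM. Histone genes held 0.000555% of fragments, against 0.00266% of TPM. Their length accounts for part of that change, since TPM divides by it. For the other changes the cause was not tested, except that fewer libraries were used where a replicate was left out. Detected genes stayed within 1.5 times of 11170, between 8970 and 13876. No alternative with posterior means was run, as the files hold counts. Depth limits genes with few fragments, such as Il4 and Ifng. No paired analysis was possible because there is 1 group.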

Other observations

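Other values outside the comparisons concern single genes that stand apart from their usual partners. Il17f exceeded Il17a in all 4 libraries, with 54475 against 908 fragments in all. Il23r, the receptor chain for interleukin-23, was at 2.14 ± 0.154 TPM while Il12rb1, its partner chain, was at 173 ± 5.103 TPM. Il7r, a marker of resting T cells, was at 2.77 ± 0.371 TPM while Ccr7, in the same list, was at 529 ± 20.5 TPM. Cd5l, a gene of the regulatory Th17 list, was at 18.7 ± 2.61 TPM. Cd8b1 was at 7.32 ± 1.16 TPM while Cd8a was under its floor of 0.113 TPM. Il23r, Il12rb1, Il7r, Cd5l and Cd8a were named after their values were seen.

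The locus Gm43305 was among the 36 variable genes but under the mean TPM needed by the naming rule, and was named after its values were seen. It was at 4.498, 0.835, 4.18 and 7.97 TPM in replicates 1 to 4 (ENSMUSG00000105703.1, chromosome 14, 54292443 to 54297343). The Y-linked genes Kdm5d and Uty were at 0.0121, 0.08098, 9.94 and 9.48 TPM and 0.0469, 0.0418, 5.61 and 5.61 TPM in replicates 1 to 4, and were left out of the variability test by its filter, with 2 and 9 fragments for Kdm5d and 5 and 3 for Uty in replicates 1 and 2.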
